A study of Homo sapiens with 12 samples.

How the data were processed

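RNA of 293Flp-In cells, a line derived from human embryonic kidney cells (HEK293) that carries a site for inserting 1 transgene at a fixed position, was measured by sequencing. Per the labels, RBM5 and RBM10 were removed with CRISPR-Cas9 and a tetracycline-inducible transgene was then inserted. There were 12 libraries in 3 groups of 4: RBM5/10-deficient cells, RBM5-Flag cells and RBM10-Flag cells. Doxycycline was present for 72 h in every group, at 0.6 ug/µL for deficient and RBM5-Flag cells and 0.06 ug/µL for RBM10-Flag cells, as the labels write the unit. Libraries were made with a stranded poly(A) kit from 200 ng of total RNA, per the labels. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

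The authors deposited 2 workbooks, RBM5-Flag against deficient and RBM10-Flag against deficient, each with 5 tables, 1 per kind of splicing event. Cassette exons, alternative 3' splice sites, alternative 5' splice sites, mutually exclusive exons and retained introns were listed separately. Per the file headers, each row held inclusion and skipping read counts for the 4 libraries of each group, effective lengths of the inclusion and skipping forms, and inclusion levels between 0 and 1. The deposited p-value and false discovery rate of each event come from the authors' own test, whose tool is not given in the sources used here. The deposited inclusion level difference is a signed score, the mean of the re-expressing cells minus that of the deficient cells. The aligner is not given in the sources used here. The genome build was hg19, per the submitters' processing notes. In every table the false discovery rate was under 0.05 and the absolute difference at least 0.1. The tables therefore hold selected events, and every test on them is a re-test of a selected list. No set of unchanged events was there to serve as a background, so no enrichment was tested and the overlap of independent lists was not computed.

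In the deposited tables, 49.3% of the 23670 pairs of inclusion and skipping cells still listed the 4 counts, and in the others a spreadsheet had joined at least 1 list into a single number. The lists were rebuilt by finding the split whose counts gave the deposited inclusion levels within 0.0011. A single split did so for 49.0% of the pairs. For 0.837% several splits did and the most even was taken, for 0.537% the last digits were lost after 15 digits, and for 0.342% the 4th count was rebuilt from its inclusion level. Differences recomputed from the rebuilt counts lay within 0.002 of the deposited value in all 11835 rows. For 26 rows of 10 genes, symbols that the spreadsheet had turned into dates were restored from the gene identifier. The 2016 events in both workbooks had identical deficient counts, so both comparisons share their control libraries. The lists carry no replicate numbers, and a library is known only by its place in the list.

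The inclusion level (PSI, percent spliced in) was computed as length-scaled inclusion reads over length-scaled inclusion plus skipping reads. The logit of PSI, with 0.5 reads added to each count, was tested with limma 3.58.1 in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg within each event type and protein. An event was called changed at an adjusted p of at most 0.05 and a difference of mean PSI of at least 10 points, rounded to 3 decimals of the PSI fraction. Events needed a mean of 20 reads per library in each group, and 1 event per exon was kept, the one with most reads. Cassette exons were told apart by their start and end, so overlapping forms of an exon count separately. RBM5-Flag and RBM10-Flag cells were compared directly on exons listed for both proteins, in 1 model over the 12 libraries. Exon features were compared between rising and falling exons with two-sided permutation tests of 100000 resamples, whose smallest p is 1e-05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.

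Positions are hg19, counted from 1. Exons were described with GENCODE 29, which is on another build, so no coordinates were carried over. An exon was matched when its gene identifier, its length and the length of at least 1 flanking intron were those of an annotated transcript. Between 92.8% and 95.8% of called exons were matched.

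Before the data were examined, the groups, tests, gene lists, alternatives and the rule for naming genes were fixed. Per protein, the named events were those with non-overlapping ranges of PSI: the 8 cassette exons with the largest rise and the 8 with the largest fall, 1 per gene, and the largest rise and fall of each other type. To these were added up to 3 further cassette exons per gene list and every listed cassette exon of the known targets. The list of known targets was written from memory and includes RBM5, RBM6 and RBM10 themselves. For RBM5-Flag against RBM10-Flag the 4 largest differences in each direction were named. Of the events this rule takes, 3 are not reported here. The alternatives were another PSI difference, adjusted p, read minimum or pseudocount, all rows in place of 1 per exon, PSI in place of its logit, the authors' false discovery rate, other rules for matching exons and leaving out each library. Leaving out exons of RBM5 and RBM10 was added after the data were seen.

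The steps were tested on simulated data with 200 changed exons. Means came from the deficient libraries, with extreme ones brought in, and 1 spread beyond counting served for all exons. Exons with high inclusion were lowered and those with low inclusion raised. In the RBM5 comparison, with 3737 exons, 95.7% of exons with a logit change of 2 were called, 53.7% at 1 and 4.69% at 0.5. In the RBM10 comparison, with 2642 exons, the shares were 95.5%, 58.7% and 11.3%. Of unchanged exons, 7 of 3537 and 2 of 2442 were called. In the data most exons passed, 3559 of 3737 and 2480 of 2642, so the adjusted threshold was less strict there. These simulated rates therefore do not carry over to the reported calls. No pair of libraries in a group agreed within sampling noise. Chi-square per exon was between 2.44 and 3.06 in every pair, so each library was counted as 1 replicate. The total depth of the libraries is unknown, since the tables hold reads of selected events only.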

Results

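Splicing was compared between 293Flp-In cells lacking the RNA-binding proteins RBM5 and RBM10 and the same cells re-expressing RBM5-Flag or RBM10-Flag, with 4 libraries in each of the 3 groups. The series asks which splicing events depend on each protein. Over the 3737 cassette exons tested for RBM5, a library held 1519558 to 1818229 reads in deficient cells and 1676477 to 1775596 in RBM5-Flag cells. Over the 2642 exons tested for RBM10, the sums were 1006317 to 1187709 and 928098 to 1167057 reads. These sums cover listed exons and are not library depths.

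Reads of the re-expressed genes were higher in the cells labelled with them. At the RBM5 exon on chromosome 3, 50142982 to 50143142 (hg19), the reads per library were 948 ± 44.9 (SD, n = 4) in deficient cells and 17968 ± 1217 in RBM5-Flag cells, with every RBM5-Flag library at 16923 or more. At the RBM10 exon on chromosome X, 47032527 to 47032596, they were 256 ± 54.3 in deficient and 2746.5 ± 374 in RBM10-Flag cells. Over the 12 listed RBM5 events the median ratio of RBM5-Flag to deficient reads was 18.4, and over the 7 listed RBM10 events the median ratio of RBM10-Flag to deficient reads was 3.16. Events of all other genes had medians of 1.01 and 0.921. Transcripts of both genes were still counted in deficient cells, so these reads check the transgenes and not the deletions.

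Most of the listed cassette exons had lower inclusion in RBM5-Flag cells. An exon of MMS19, a factor of iron-sulfur protein assembly (ENSG00000155229, chromosome 10, 99236592 to 99236676, in a transcript not annotated as coding), fell from 95.2% ± 2.10 to 22.9% ± 6.59 (SD, n = 4 per group). Exons of the receptor kinase FGFR3 (chromosome 4, 1804641 to 1804791, coding), the metalloprotease ADAM15 (chromosome 1, 155028178 to 155028328) and the peptidase DPP7 (chromosome 9, 140007813 to 140007948, coding) fell from 83.9% ± 1.52 to 20.5% ± 4.50, from 95.0% ± 2.01 to 30.5% ± 2.65 and from 71.1% ± 10.9 to 5.74% ± 1.39. A 162-nt exon of ELMOD3 was included in all deficient libraries, at 100% ± 0, and in 35.0% ± 11.7 of RBM5-Flag transcripts. The glutaminase gene GLS2 and RP11-345J4.5 completed the exons with the largest falls, together with RBM10 itself. Fewer exons rose, among them exons of the long noncoding gene RP11-43F13.1 (from 38.8% ± 4.10 to 88.6% ± 4.12) and of the transcription factor DMTF1, in its 5' UTR (from 8.73% ± 6.90 to 54.7% ± 12.4).

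In total 3559 of 3737 exons passed the limma test, 679 with higher and 2880 with lower inclusion in RBM5-Flag cells, in 2366 genes. The median rise was 15.6 PSI points, and falling exons fell by 16.8 points at the median. The ranges of the 2 groups did not overlap for 2924 called exons, where chance gives 2.86% of unselected exons. The adjusted p of limma was 1.77e-05 for MMS19, 8.82e-06 for FGFR3 and 2.15e-05 for DPP7. Several of the largest rises rested on few reads, 23.5 per library for DMTF1, 35.4 for CRLS1, 42.5 for NUP62, 26 for the RNA polymerase subunit gene POLR2F (from 24.9% ± 5.23 to 72.3% ± 22.6), 24.9 for SYCP2L (from 42.3% ± 14.4 to 84.5% ± 18.5) and 40.8 for KRBOX4 (from 11.7% ± 9.97 to 52.6% ± 8.27). The list had been selected by the authors on the same libraries, so the share that passes is not a rate of changed exons. At a PSI difference of 20 points, 1226 exons passed.

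**Figure D1:**
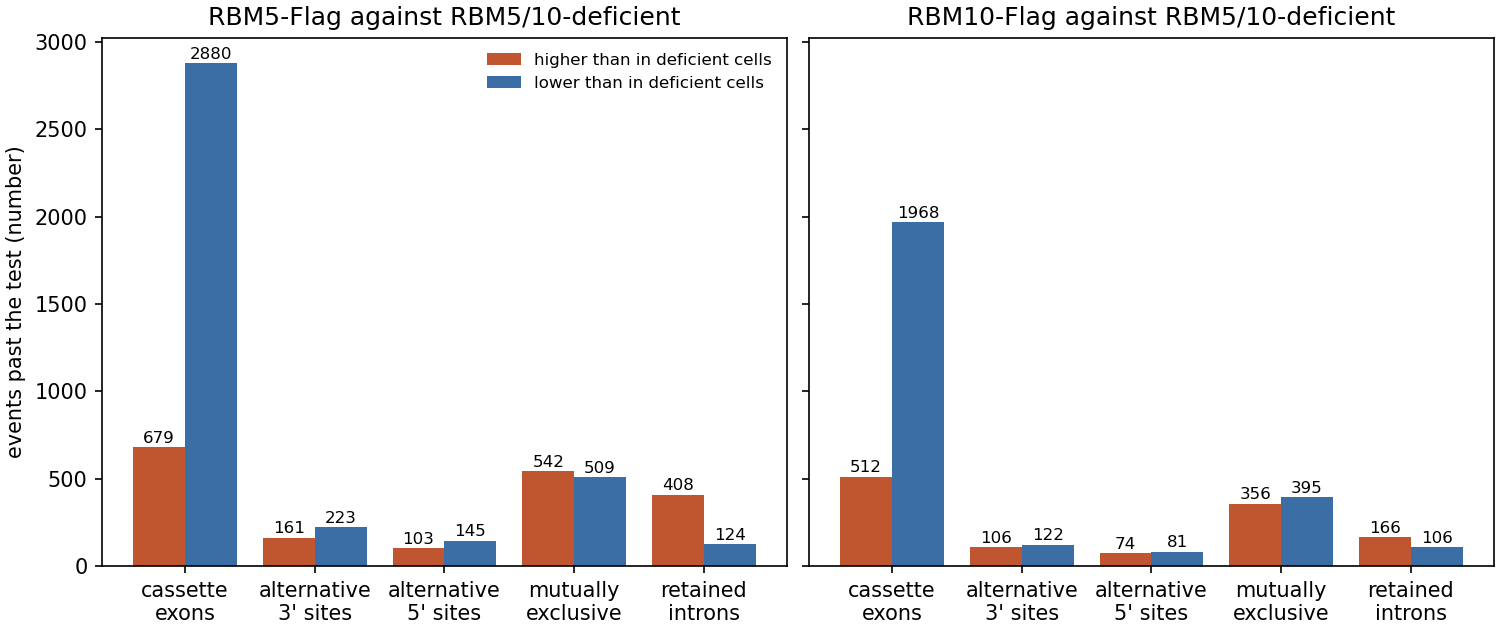
Number of splicing events past the limma test for each event type (horizontal axis), higher (orange) or lower (blue) in RBM5-Flag cells (left) or RBM10-Flag cells (right) than in RBM5/10-deficient cells, with 4 libraries per group. Cassette exons fell in most cases (2880 and 1968), and retained introns rose more often than they fell.

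Genes listed from memory as targets of RBM5, RBM6 or RBM10 held 18 exons changed with RBM5, in 10 of the 18 genes. Of these exons 4 lay in RBM5 itself, whose reads rose with its transgene. The cassette exon of NUMB, an adaptor that restrains Notch signalling (chromosome 14, 73745989 to 73746132, coding), fell from 68.9% ± 5.18 to 54.5% ± 7.41 (SD, n = 4 per group), with a limma adjusted p of 0.0177. The exon of the death receptor FAS that encodes its transmembrane part (chromosome 10, 90770510 to 90770572) fell from 95.9% ± 1.31 to 85.7% ± 3.02, and an exon of the DNA methyltransferase DNMT3B (chromosome 20, 31374308 to 31374433) fell from 93.8% ± 2.28 to 60.3% ± 5.80. An exon of CASP2, a caspase (chromosome 7, 142997473 to 142997533), fell from 19.7% ± 6.38 to 6.61% ± 2.41. In RBM10, whose transgene these cells do not carry, a 70-nt coding exon fell from 85.0% ± 3.53 to 14.9% ± 5.80. In RBM6, a relative of both proteins, an exon (chromosome 3, 50036873 to 50036946) rose from 46.6% ± 3.30 to 58.7% ± 1.43. Without the 2nd or 4th listed RBM5-Flag or the 3rd listed deficient library the change of FAS was -9.69 to -9.15 points, short of the threshold of 10. A further DNMT3B exon (chromosome 20, 31372564 to 31372665) fell from 97.2% ± 2.48 to 87.3% ± 6.17, a change that was -9.93 to -7.24 points without the 1st or 4th listed RBM5-Flag or the 1st, 3rd or 4th listed deficient library.

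Exons of the other gene groups were mostly skipped more, as were 80.9% of all called exons. Among splicing regulators 22 of 111 had a changed cassette exon, 17 with only lower inclusion, 4 only higher inclusion and 1 both; PTBP1, a repressor of neuronal exons, fell from 73.9% ± 4.52 to 38.9% ± 5.34 and the kinase gene CLK2 from 77.5% ± 1.58 to 48.9% ± 3.08, while an exon of the kinase gene SRPK2 rose from 49.5% ± 18.7 to 86.4% ± 6.75. Among spliceosome core genes 11 of 104 had a changed cassette exon, 9 with only lower inclusion and 2 only higher inclusion, with PRPF40B falling from 93.7% ± 4.06 to 63.9% ± 7.99. Among Notch and endocytic adaptor genes 17 of 69 had a changed cassette exon, 15 with only lower inclusion and 2 only higher inclusion; a 12-nt exon of dynamin DNM1 fell from 78.6% ± 2.88 to 36.3% ± 1.72 and an exon of the clathrin adaptor AP2M1 from 47.3% ± 2.68 to 20.8% ± 1.11. All 9 apoptosis genes with a changed exon, of 53 in that list, had lower inclusion, such as the survivin gene BIRC5 (from 59.8% ± 5.54 to 35.0% ± 5.61). Among chromatin regulators 45 of 134 had a changed cassette exon, 32 with only lower inclusion, 11 only higher inclusion and 2 both, and INO80E fell from 76.4% ± 2.08 to 36.4% ± 3.08. Among DNA repair and cell cycle genes 46 of 156 had a changed cassette exon, 42 with only lower inclusion, 2 only higher inclusion and 2 both, and the DNA polymerase gene POLM fell from 87.6% ± 12.1 to 42.5% ± 4.37. Among cytoskeleton and small GTPase genes 59 of 151 had a changed cassette exon, 42 with only lower inclusion, 9 only higher inclusion and 8 both, and spectrin SPTAN1 fell from 93.5% ± 0.734 to 49.6% ± 2.11. Among kinase and growth signalling genes 36 of 143 had a changed cassette exon, 23 with only lower inclusion, 6 only higher inclusion and 7 both; the kinase MAPK3 fell from 96.3% ± 1.62 to 43.5% ± 4.60 and the phosphatase PTPRS from 83.2% ± 1.64 to 31.8% ± 1.62. Adjusted over the list alone, each of the 9 lists gave the same number of genes as over all exons tested. Nearly all exons in the authors' selection passed, so this could hardly come out otherwise.

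Retained introns went the other way with RBM5, 408 of 532 called introns having higher retention. An intron of FUK (chromosome 16, 70500858 to 70501276) rose from 16.0% ± 2.13 to 65.0% ± 19.8 (SD, n = 4 per group), and one of ZNF517 fell from 75.8% ± 28.96 to 22.1% ± 8.38. Of 384 called alternative 3' splice sites 223 had lower use of the longer exon, the largest fall being in TP53I13 (from 87.4% ± 6.83 to 21.5% ± 4.24) and the largest rise in HOXB-AS1 (from 36.9% ± 8.40 to 74.2% ± 20.9). Of 248 alternative 5' splice sites 145 fell, among them the phosphofructokinase gene PFKM (from 90.1% ± 3.28 to 32.1% ± 1.74), and FN3KRP rose from 31.5% ± 20.2 to 81.0% ± 5.84. Mutually exclusive exons were called 1051 times, 542 with higher and 509 with lower use of the exon that the authors' deposited table counts as included, and at a PSI difference of 20 points 91 and 97; ZDHHC16 rose from 32.7% ± 6.54 to 81.1% ± 7.50 and ADAM15 fell from 53.004% ± 22.1 to 5.57% ± 2.12. With limma, the adjusted p was 0.00154 for FUK, 5.9e-05 for TP53I13 and 1.35e-05 for PFKM.

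Most of the listed cassette exons also had lower inclusion in RBM10-Flag cells. A 21-nt coding exon of ELAC2, a tRNA-processing nuclease (ENSG00000006744, chromosome 17, 12906796 to 12906816), fell from 97.4% ± 1.72 to 27.5% ± 4.31 (SD, n = 4 per group). Exons of the ubiquitin ligase RNF167 (chromosome 17, 4846474 to 4846579) and the tRNA phosphotransferase TRPT1 (chromosome 11, 63991572 to 63991634, coding) fell from 82.4% ± 8.52 to 17.9% ± 4.03 and from 93.7% ± 4.04 to 29.6% ± 3.86. TMEM106C fell from 81.1% ± 3.93 to 24.4% ± 1.93, MYOM2 from 78.6% ± 5.24 to 18.3% ± 6.94 and the 8-nt exon of PITPNB from 98.6% ± 2.83 to 41.9% ± 11.7. The largest rises were smaller, such as the chromatin-remodelling subunit gene NFRKB in its 5' UTR (from 19.1% ± 8.53 to 56.4% ± 9.77) and DPY19L3 (from 33.6% ± 7.08 to 69.8% ± 2.98).

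Of 2642 exons tested 2480 passed, 512 with higher and 1968 with lower inclusion, in 1793 genes. The median rise was 14.7 points, and falling exons fell by 16.2 points at the median. Ranges did not overlap for 1974 called exons. The adjusted p of limma was 0.00014 for ELAC2, 0.00011 for TRPT1 and 0.00214 for NFRKB, which had 26.4 reads per library. This list was selected like that of RBM5, and the doxycycline dose of RBM10-Flag cells differed from that of the deficient cells. At a PSI difference of 20 points 750 exons passed, and at an adjusted p of at most 0.01 1572.

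**Figure D2:**
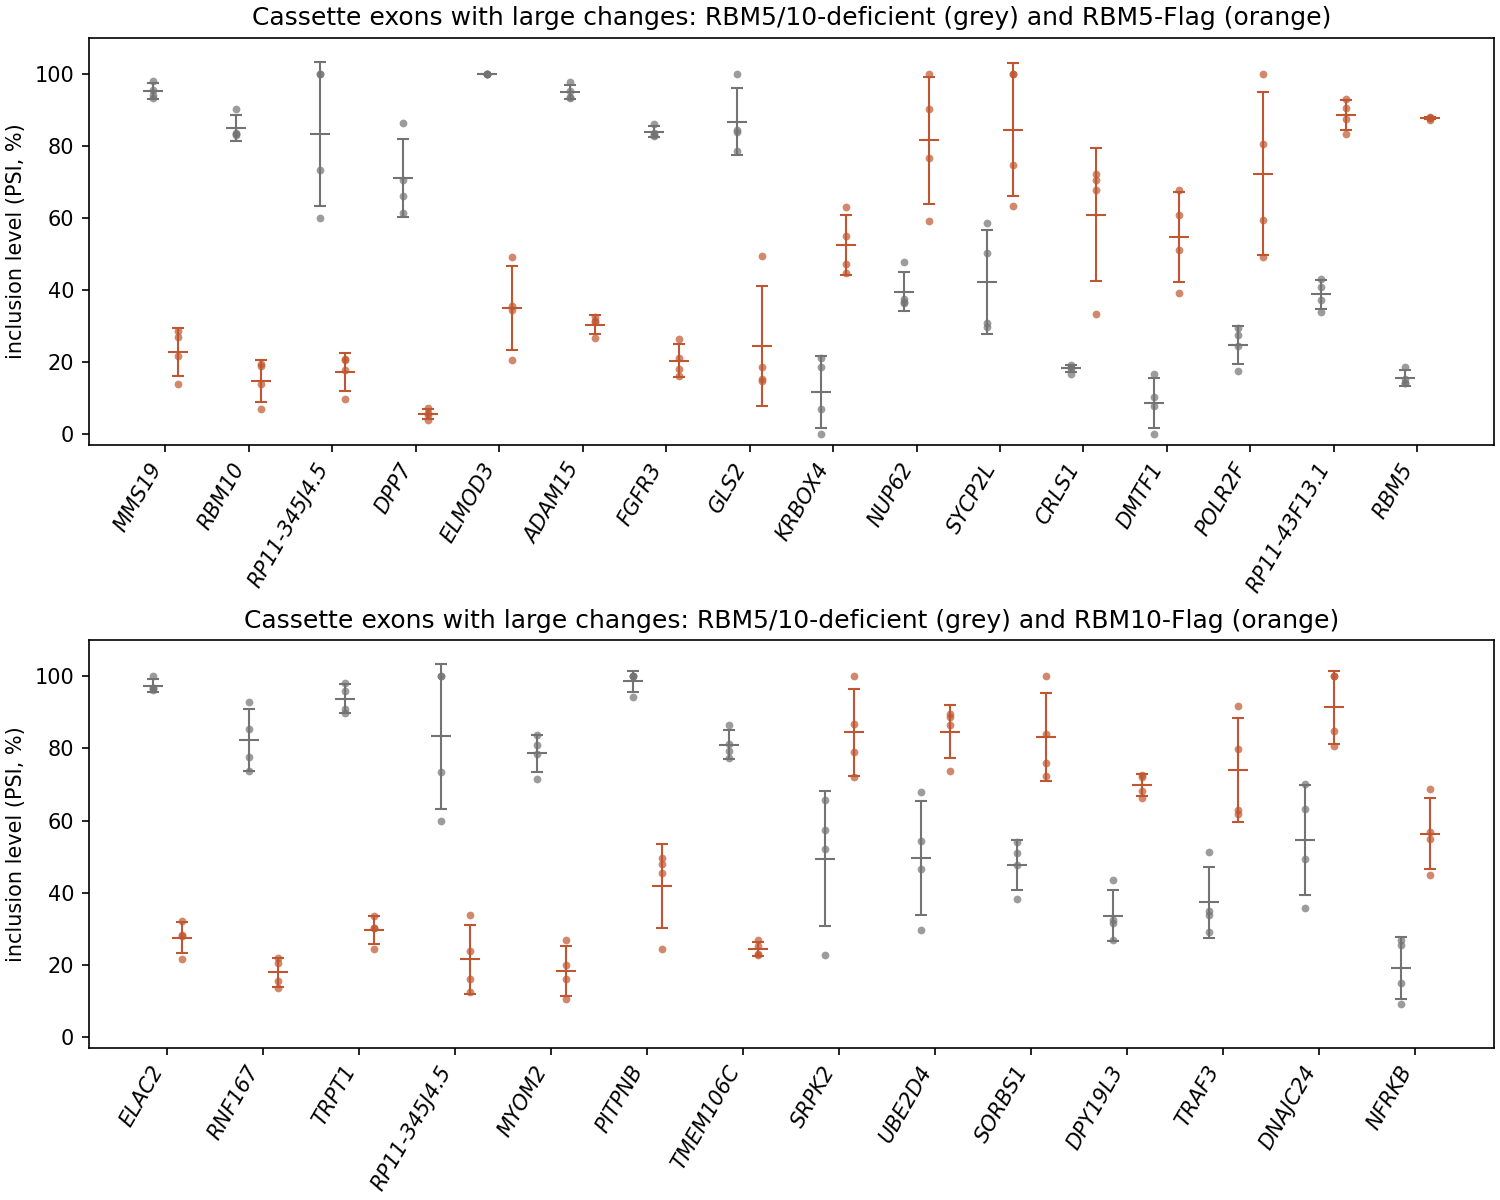
Inclusion level (PSI, percent) of cassette exons among those with the largest changes, for RBM5-Flag (top) and RBM10-Flag (bottom). Each point is 1 library, grey for RBM5/10-deficient and orange for re-expressing cells, with a line at the mean and bars of 1 SD (n = 4). MMS19 goes from 95.2% ± 2.10 to 22.9% ± 6.59 in the top panel and ELAC2 from 97.4% ± 1.72 to 27.5% ± 4.31 in the bottom panel.

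Among known targets, NUMB fell in RBM10-Flag cells from 68.9% ± 5.18 to 42.8% ± 3.86 (SD, n = 4 per group). FAS fell from 95.9% ± 1.31 to 69.8% ± 7.10. Both changes were at the exons that also fell with RBM5. The RBM6 exon that rose with RBM5 fell from 46.6% ± 3.30 to 33.0% ± 3.64 with RBM10. With limma, the adjusted p was 0.000882 for NUMB, 0.000131 for FAS and 0.00751 for this RBM6 exon. DNMT3B fell at 3 exons, the largest change being from 93.8% ± 2.28 to 56.7% ± 2.06 (chromosome 20, 31374308 to 31374433). A 74-nt coding exon of RBM5 (chromosome 3, 50137965 to 50138038), whose transgene these cells do not carry, fell from 98.1% ± 2.28 to 54.0% ± 3.54. LUC7L, a protein bound to the U1 particle, fell from 39.1% ± 4.91 to 9.23% ± 1.64 in its 5' UTR exon. Another exon of RBM6 rose from 46.4% ± 4.43 to 59.9% ± 9.24 (chromosome 3, 50012756 to 50012825), with a limma adjusted p of 0.0340 that became 0.0502 to 0.0833 without the 1st, 2nd or 3rd listed deficient or the 2nd, 3rd or 4th listed RBM10-Flag library. DLG4 fell from 25.6% ± 3.26 to 15.1% ± 3.60, a change that was -9.86 to -9.46 points without the 1st or 2nd listed deficient or the 1st or 3rd listed RBM10-Flag library. In all, 10 of the 18 known targets had a changed exon, among them RBM10 itself, whose reads rose with its transgene.

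With RBM10 exons of these gene groups were again mostly skipped more, as were 79.4% of all called exons. Among splicing regulators 20 of 111 had a changed cassette exon, 10 with only lower inclusion, 7 only higher inclusion and 3 both; the RNA-binding protein gene PCBP2 fell from 78.2% ± 1.59 to 36.6% ± 1.504 and CLK2 from 77.5% ± 1.58 to 35.2% ± 1.71, and the fall of RBM23 (from 76.0% ± 17.2 to 45.7% ± 7.06) had a limma adjusted p of 0.0351, which became 0.0514 to 0.0776 when any 1 RBM10-Flag library was left out. Among spliceosome core genes 15 of 104 had a changed cassette exon, 14 with only lower inclusion and 1 only higher inclusion, with LUC7L3 falling from 53.8% ± 3.08 to 20.6% ± 3.18. Among Notch and endocytic adaptor genes 14 of 69 had a changed cassette exon, 12 with only lower inclusion and 2 only higher inclusion, with a dynamin-related DNM1L exon falling from 68.1% ± 6.73 to 35.4% ± 2.97. Among apoptosis genes 7 of 53 had a changed cassette exon, 6 with only lower inclusion and 1 only higher inclusion; CASP8 fell from 51.8% ± 4.56 to 32.8% ± 1.30 and the 5' UTR exon of BID rose from 35.4% ± 14.4 to 66.7% ± 15.3. Among chromatin regulators 33 of 134 had a changed cassette exon, 21 with only lower inclusion, 8 only higher inclusion and 4 both; the acetyltransferase gene CREBBP fell from 90.5% ± 3.25 to 39.8% ± 4.09. Among DNA repair and cell cycle genes 34 of 156 had a changed cassette exon, 32 with only lower inclusion and 2 only higher inclusion, with CEP290 falling from 90.4% ± 3.29 to 54.1% ± 1.92. Among cytoskeleton and small GTPase genes 45 of 151 had a changed cassette exon, 37 with only lower inclusion, 3 only higher inclusion and 5 both; TBC1D23 fell from 78.6% ± 2.50 to 38.6% ± 4.44 and the phosphatase gene MTMR3 from 81.7% ± 5.90 to 49.2% ± 4.44. Among kinase and growth signalling genes 28 of 143 had a changed cassette exon, 25 with only lower inclusion, 2 only higher inclusion and 1 both; PTPRS fell from 83.2% ± 1.64 to 42.0% ± 2.67 and TEAD2 from 80.8% ± 2.87 to 50.6% ± 3.01. Adjusted over the list alone, the 9 lists again gave the same numbers, which the authors' selection again left little room to change.

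Of 272 called retained introns 166 rose with RBM10, the largest being in PLEKHG4 (from 32.8% ± 8.45 to 74.9% ± 19.8 (SD, n = 4 per group)), and an intron of ZNF517 fell from 75.8% ± 28.96 to 21.7% ± 9.04 as with RBM5. Alternative 3' splice sites split into 106 rising and 122 falling, but into 14 and 36 at a PSI difference of 20 points. C16orf93 rose from 48.0% ± 4.80 to 80.3% ± 7.19 and DNM1 fell from 76.5% ± 11.7 to 34.0% ± 8.37. Alternative 5' splice sites split into 74 rising and 81 falling, and into 16 and 18 at a PSI difference of 20 points. At a limma adjusted p of at most 0.01 they split into 22 and 40. The interferon-signalling factor STAT2 rose from 44.1% ± 8.48 to 73.0% ± 3.49 and the ubiquitin ligase UBR1 fell from 86.2% ± 12.9 to 36.4% ± 4.97. Of 751 mutually exclusive exons 356 rose and 395 fell, but 71 rose and 52 fell at a PSI difference of 20 points, so neither direction prevailed at both settings. Among them RBM10 itself, whose reads rose with its transgene, rose from 22.8% ± 8.53 to 73.2% ± 2.17, and MPV17 fell from 81.3% ± 6.73 to 37.1% ± 4.03. The limma adjusted p was 0.0119 for PLEKHG4 and 0.00224 for UBR1.

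Many exons changed with both proteins. 1275 exons were called for RBM5 and for RBM10, 35.8% of the RBM5 and 51.4% of the RBM10 exons. Of these 1221 moved the same way, 1054 lower and 167 higher with both, and 54 moved in opposite directions. The last number was 31 when exons were matched with both flanking exons, 32 without the 3rd listed deficient library and 2 at a PSI difference of 20 points. At that difference 299 were called for both. NUMB, FAS, DNMT3B, CLK2, MTMR3 and PTPRS were among those that fell with both. Of the called retained introns 147 were shared, 143 of them with the same direction. Among the 1267 exons listed for both as the same event, PSI differences correlated at 0.764 across exons, which are not independent replicates, and 97.2% had the same direction. Both comparisons use the same deficient libraries, and 50 simulations without any effect gave 0.490 and 66.2%. These did not select exons as the lists had been. In a check chosen after the results were seen, simulated exons were kept where both differences reached 10 points. The 230 kept exons, pooled over all simulations, were 0.363% of all and gave 0.939 and 99.1%. This check selected by size and not by a false discovery rate, so it does not match the lists. It shows that selection against shared libraries can give high values without an effect. Neither the correlation nor the shared direction alone is therefore taken as evidence of a shared effect. The covariance was 0.0215 against 0.000597 in the simulations without selection. Listed exons had to differ by at least 10 points in both comparisons, which raises the covariance by itself. It is therefore not taken as evidence of a shared effect either. With the deficient libraries split into 2 and 2, so that the comparisons shared none, the correlation was 0.702 to 0.721. The share with the same direction was then 97.1% to 97.2%. These observed values are on exons selected with all 4 deficient libraries. Unchanged simulated groups gave 0 exons called for both. These simulated exons were not selected, and without changed exons the adjusted threshold is stricter than in the data. The 0 is therefore not a chance level for the 1275 exons.

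**Figure D3:**
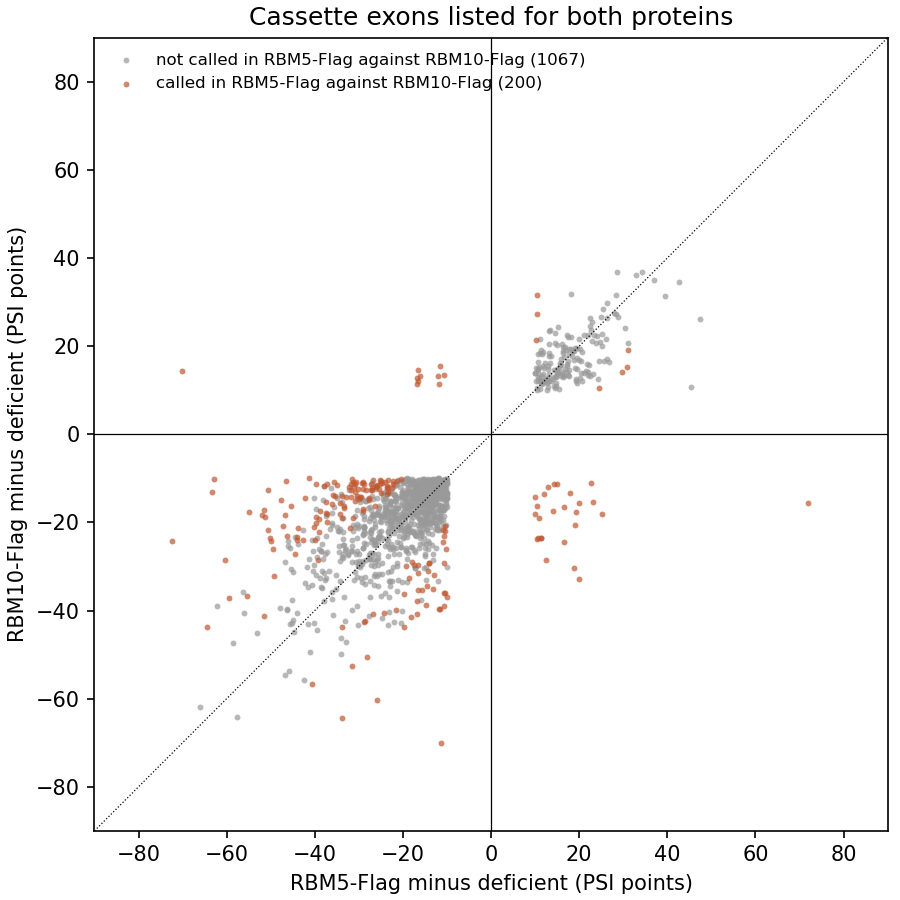
Change of inclusion level with RBM5-Flag (horizontal axis, PSI points) and RBM10-Flag (vertical axis, PSI points) against RBM5/10-deficient cells for the 1267 cassette exons listed for both. Each point is 1 exon, orange where RBM5-Flag and RBM10-Flag differed in the direct test (200), the dotted line marks equal change, and the empty band around 0 comes from the selection of exons changed by at least 10 points.

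Comparing the re-expressing cells with each other, 200 of the 1267 exons differed, 75 with higher inclusion in RBM5-Flag and 125 in RBM10-Flag cells. The ELAC2 exon was at 97.4% ± 1.72 in deficient, 86.1% ± 3.13 in RBM5-Flag and 27.5% ± 4.31 in RBM10-Flag cells (SD, n = 4 per group). The Wnt effector TCF7L2 (114724315 to 114724383 on chromosome 10, coding) was at 65.8% ± 12.9 in deficient, 85.8% ± 3.66 in RBM5-Flag and 32.9% ± 12.1 in RBM10-Flag cells, and the vesicle fusion gene SNAP25 (chromosome 20, 10265372 to 10265420) at 73.0% ± 11.2 in deficient, 91.9% ± 7.47 in RBM5-Flag and 42.7% ± 7.28 in RBM10-Flag cells. On the other side, DPP7 (chromosome 9, 140007658 to 140007739) was at 95.2% ± 2.59 in deficient, 32.3% ± 2.90 in RBM5-Flag and 85.0% ± 6.75 in RBM10-Flag cells, FGFR3 at 83.9% ± 1.52 in deficient, 20.5% ± 4.50 in RBM5-Flag and 70.7% ± 6.56 in RBM10-Flag cells and MMS19 at 95.2% ± 2.10 in deficient, 22.9% ± 6.59 in RBM5-Flag and 70.9% ± 12.8 in RBM10-Flag cells. Among the 1267 exons, the largest differences were at exons of RBM5 and RBM10 themselves. The direct limma test gave an adjusted p of 0.000692 for ELAC2, 0.000299 for TCF7L2, 0.000386 for SNAP25, 0.000462 for DPP7, 9.15e-06 for FGFR3 and 0.00092 for MMS19. Of the 200 exons 164 moved the same way with both proteins, 116 more with RBM5 and 48 more with RBM10, and 36 moved in opposite directions. The doses of doxycycline differed between these groups, so protein and dose cannot be separated, and 95 exons differed by 20 points or more.

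Rising and falling exons differed in their surroundings. Intron lengths were measured to the flanking exons of the deposited event, so some span other exons. The 3760 nt upstream of the RBM10 exon at 47034418, for example, hold the exon at 47032527 to 47032596. With RBM5, the upstream intron measured in this way had a median length of 4432 nt for rising exons against 1183 nt for falling exons. The downstream intron had 5284 against 1204 nt. With RBM10, these were 3808 against 1536 nt and 4029 against 1502.5 nt. Each of these differences had an adjusted p of 1.43e-05, from the smallest p the permutation test can give, in a family of 10 tests. Rising exons were longer, 118 against 109 nt with RBM5 (permutation test, adjusted p = 0.00779) and 129 against 98 nt with RBM10 (adjusted p = 1.43e-05). The difference for RBM5 was not past the threshold among exons that changed by 20 points, where it was 10 nt with an adjusted p of 0.102 by permutation. Exons of a length divisible by 3 made up 42.7% of rising and 42.8% of falling exons with RBM5 (permutation test, adjusted p = 0.966), and 41.2% and 44.7% with RBM10 (adjusted p = 0.179). In deficient cells, exons that fell with RBM5 started at a median inclusion of 86.3% and those that rose at 45.9%, and with RBM10 at 85.2% and 49.5% (permutation tests, adjusted p = 1.43e-05 for each). An exon included above 90% cannot rise by 10 points, so the starting levels are in part set by the selection, and exons are not independent replicates.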

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

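The tests on reads of the transgenes, on different events of 1 exon and on doxycycline dose, and the counts of other splits of the libraries, were chosen after the results were seen.

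In groups of 4 libraries of the named events, 21 of 258 had 1 library far from the other 3, and chance gives about 1 in 20. In deficient cells, with the value of the library that stood apart and of its nearest neighbour, these were NUP62 (47.8% against 37.7%), RBM10 (90.3% against 83.5%), BCLAF1 (78.0% against 75.6%), HDAC6 (88.4% against 100%), SPTAN1 (92.4% against 93.8%), ELAC2 (100% against 96.9%), PITPNB (94.3% against 100%), SMC5 (81.7% against 86.1%), TBC1D23 (82.3% against 77.8%) and TEAD2 (85.1% against 79.7%). The RBM10 and BCLAF1 exons are in both tables with the same deficient libraries and so count 2 times. The rule does not weigh the size of the gap, which was small at SPTAN1 and BCLAF1. At HDAC6 and PITPNB the other deficient libraries were tied at 100%, where the chance share may not hold. Deficient libraries also stood apart at the DNM1 alternative 3' splice site (59.0% against 82.1%) and the PLEKHG4 retained intron (20.2% against 35.2%). In RBM5-Flag cells they were CRLS1 (33.5% against 67.7%), GLS2 (49.5% against 18.6%), AP2M1 (22.5% against 20.4%) and BIRC5 (26.6% against 37.1%), and in RBM10-Flag cells PITPNB (24.5% against 45.6%), RBM6 (46.2% against 62.8%) and ZRANB2 (39.2% against 37.6%).

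In the direct limma test, 8 named exons differed between RBM5-Flag and RBM10-Flag cells. Inclusion in RBM5-Flag minus RBM10-Flag cells was 87.5 points for RBM5, 58.7 for ELAC2, 52.9 for TCF7L2 and 49.2 for SNAP25. It was -84.6 points for RBM10, -52.7 for DPP7, -50.3 for FGFR3 and -48.0 for MMS19.

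Exons of RBM5 in RBM5-Flag cells and of RBM10 in RBM10-Flag cells changed strongly, the RBM5 exon on chromosome 3, 50142510 to 50142575, from 15.7% ± 2.16 to 87.7% ± 0.319. A candidate explanation is that reads of the transgene were counted at these exons. The median ratio of reads at the gene's own events was 18.4 for RBM5 and 3.16 for RBM10, the smaller of which is above the 3 that this explanation needs. The ratios ranged from 2.15 to 10.7 over the RBM10 events, and a change in splicing of the native transcripts was not separable from it. Without exons of both genes 3552 and 2476 cassette exons were called.

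A further 34 exons outside RBM5 and RBM10, in 27 genes such as SNAP25 and TCF7L2, moved in opposite directions with the 2 proteins when compared as the same event. Overlapping forms of an exon, such as those of CTNND1 and of ZNF664, count separately in that number. Of the 54 exons called in opposite directions 31, or 57.4%, were so with both flanking exons matched. This matching used the event with most reads in each comparison. An exon thus dropped out where those events differed, even if both comparisons listed a common event, so the share may be too low. Compared as the same event, 36 exons moved in opposite directions. Different deposited events of an exon may account for part of the 54 and stay open. A single library does not account for the 36 exons that moved in opposite directions as the same event, those of RBM5 and RBM10 included, since 100% of them stayed opposite with the direct test passed in all 12 fits that left out a library; by selection these exons differ by about 20 points or more, and of all 200 exons called in the direct test 75.5% were called in every such fit. The dose of doxycycline cannot be told apart from the protein, because the groups share 0 doses, and a difference between the proteins stays open beside it.

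Other splits of the 8 libraries into groups of 4 were counted for each comparison. Of 35 splits only the real one, 1 split, gave as many calls. The real and the highest other counts for RBM5 were 3559 and 1 for cassette exons, 384 and 2 for alternative 3' splice sites, 248 and 0 for alternative 5' splice sites, 1051 and 1 for mutually exclusive exons, 532 and 1 for retained introns. For RBM10 they were 2480 and 0 for cassette exons, 228 and 1 for alternative 3' splice sites, 155 and 0 for alternative 5' splice sites, 751 and 1 for mutually exclusive exons, 272 and 1 for retained introns. Because the authors had chosen these events with the real groups, these splits do not decide whether chance can be excluded. For RBM5-Flag against RBM10-Flag, splits of the 8 re-expressing libraries gave 200 calls for the real split and at most 1 for the other splits, 1 of 35 again. These exons, too, had been chosen with the real groups, so this count does not decide it either.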

How the results depend on the processing

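Leaving out exons of RBM5 and RBM10 and the block by place in the list were chosen after seeing the data, and the other alternatives before. Of 265 recomputed counts of changed events and exons 244 lay within 1.5 times the reported count and 21 did not, all of the latter at a PSI difference of 20 points or an adjusted p of at most 0.01, which by construction keep fewer events. Of 324 recomputed counts of genes in lists 304 lay within 1.5 times and 20 did not, at the same settings. Part of this agreement was set in advance. Every listed event already had a false discovery rate under 0.05 and a difference of at least 10 points. For counts against deficient cells, a PSI difference of 5 points or the authors' false discovery rate could therefore hardly change the result. At 20 points, cassette exons fell to 1226 for RBM5 and 750 for RBM10, exons called for both to 299 and exons differing between RBM5-Flag and RBM10-Flag to 95. The other types gave, for RBM5 and RBM10, 118 and 50 alternative 3' splice sites, 76 and 34 alternative 5' splice sites, 188 and 123 mutually exclusive exons, 146 and 65 retained introns, and together 528 and 272. At an adjusted p of at most 0.01, RBM10 had 1572 cassette exons, 124 alternative 3' splice sites, 62 alternative 5' splice sites, 447 mutually exclusive exons, 155 retained introns and 788 of these 4 types together, and RBM5 164 alternative 5' splice sites. The gene lists held, at 20 points for RBM5 and RBM10, 4 and 6 genes (known targets), 7 and 6 genes (splicing regulators), 3 and 7 genes (spliceosome core), 10 and 6 genes (Notch and endocytic adaptors), 3 and 1 genes (apoptosis), 21 and 14 genes (chromatin regulators), 20 and 10 genes (DNA repair and cell cycle), 24 and 20 genes (cytoskeleton and small GTPase regulators), 10 and 6 genes (kinases and growth signalling); at 0.01 RBM10 had 9 spliceosome core and 4 apoptosis genes. The longer exons among those rising with RBM5 differed by 10 nt at 20 points and no longer passed, and the cause was not tested beyond the smaller number of exons. The other 29 recomputed exon features kept their direction or stayed on their side of the threshold. Leaving out each library gave 3182 to 3290 cassette exons for RBM5, 2154 to 2245 for RBM10, 1959 to 1998 and 1132 to 1227 other events, 1092 to 1184 exons called for both and 160 to 207 in the direct test. Named events came from the authors' selection, and many were picked for large changes, so their stability was in part set in advance. Of 129 named events 120 stayed called under all settings that refitted them, 0 reversed, and the 9 others lost the call only in fits that left out 1 library. Besides FAS, a DNMT3B exon, RBM6, DLG4 and RBM23 these were TNRC6A at 24741574 (adjusted p of 0.0557 to 0.0704 with limma without the 1st listed deficient or the 1st or 4th listed RBM10-Flag library, and -9.41 points without the 2nd listed deficient library) and at 24807228 (-9.89 to -8.92 points without the 2nd or 4th listed deficient or the 3rd listed RBM10-Flag library), RBM10 at 47030427 (-9.18 points without the 3rd listed RBM5-Flag library) and RBM5 at 50142982 (a rise of 9.83 points without the 3rd listed deficient library). GEO's labels number the replicates in each group, but the deposited lists do not give these numbers, so only the place in the list could serve as a replicate block. With it limma called 3432 cassette exons for RBM5 and 2362 for RBM10, 2157 and 1339 other events, 1179 exons for both and 178 in the direct test. Deviations from the group mean correlated at -0.0797 to 0.0648 between libraries at the same place of 2 groups, and in no comparison did every library correlate best with its own place, so the places were not taken as pairs. Matching RBM5 and RBM10 exons by any overlap was not run for the direct test, since reads of different exons would be compared.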

Other observations

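The counts of genes with several falling exons, the shares of annotated locations and the tests on the lengths of retained introns and alternative splice site segments were chosen after the results were seen.

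Several genes lost inclusion at several exons. With RBM5, 460 of 1950 genes with a falling exon had at least 2 separate, non-overlapping ones, and with RBM10 276 of 1453. BECN1, which acts in autophagy (chromosome 17, 40963673 to 40971627), had 6 separate falling exons with RBM5 and 5 separate falling exons with RBM10, and no rising exon. PPOX, an enzyme of haem synthesis, had 6 separate falling exons with RBM5, and the repair polymerase POLL had 5 separate falling exons. The mannosidase gene MAN2B1 had 4 separate falling exons with RBM10. Other such genes had rising exons too. DMKN had the most falling exons with RBM5, 7 beside 3 rising exons, and with RBM10 it had 5 beside 2. PHYKPL had 5 falling exons beside 1 rising exon with RBM5. These genes were picked for their values, and genes with several rising exons were not counted.

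The annotated places of rising and falling exons were counted without a test. With RBM5, 40.3% of matched rising exons were coding and 22.0% lay in a 5' UTR, against 61.4% and 7.79% of falling exons. With RBM10 the shares were 35.2% and 19.2% against 64.3% and 7.10%. Retained introns that rose with RBM5 were short, with a median of 183.5 nt against 525 nt for those that fell, and with RBM10 288.5 against 384.5 nt (permutation tests, adjusted p = 6e-05 and 0.0300 in a family of 6). The segment between alternative 5' splice sites was shorter where its use rose, with medians of 87 against 208 nt with RBM5 and 91 against 168 nt with RBM10 (permutation tests, adjusted p = 6e-05 and 0.00542). For alternative 3' splice sites the medians were 91 against 89 nt and 86 against 103 nt, and neither difference passed (permutation tests, adjusted p = 0.940 and 0.856).

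Introns beside rising exons were longer, 4.09 times those beside falling exons with RBM5 and 2.69 times with RBM10, as the ratio of medians of the mean (geometric) flanking intron length. These lengths run to the flanking exons of the deposited event and may span other exons. How far that sets the ratios was not tested. The tables argue against the starting inclusion level as the whole cause: within 5 equal bins of the inclusion level in deficient cells the median ratio was 3.14 with RBM5 and 2.28 with RBM10, over the 3 bins with at least 20 exons of each direction. That minimum was set after the highest bin proved to hold 0 rising exons. They argue in the same way against read depth, with median ratios of 3.85 and 2.69 over 5 bins of the reads per library. Genes with long introns stay open: relative to the median intron of the same gene the ratio was 1.71 with RBM5 and 1.47 with RBM10, and the latter lies between the bounds fixed beforehand, so a gene-wide trend may account for part of the pattern, and no biological explanation was tested.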
